A study of Schizosaccharomyces pombe with 49 samples.

How the data were processed

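The series holds 49 RNA sequencing libraries of fission yeast, all from bulk RNA of mitotic or meiotic cells. Count tables of 46 libraries were used, together with tables of 2 strains that give a comparison with another library in place of counts. The remaining library, a wild type of the mat1Msmt0 mating type in YEA medium, was not analysed here. Per the labels, libraries were made with the ScriptSeq v2 or the Ultra II Directional kit and read on a MiSeq or a NextSeq, and neither is tied to a sample. Reads were trimmed with Trimmomatic and aligned with STAR, per the submitters' processing notes. Versions, genome build and annotation are not given in the sources used here.

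The deposited counts are whole reads per gene, not normalised, in the layout of STAR gene counting, with a column without strand and a column for each strand setting. The authors' comparison tables give a log2 fold change per gene, scaled by the authors, per the file headers. They also give an adjusted p-value, called a q-value per the file headers. The tool behind those comparisons is not given in the sources used here. Their 4 value columns name no sample and were not used, and the tables share 1 of those columns (6564 of 6564 genes equal). They were therefore not set against each other.

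The column rule was fixed before the data were examined. A set of libraries used the strand column with the larger total if it held at least 4 times the other column in every library, and otherwise the column without strand. The tor2-ts6 h90 libraries, the GFP-Pir1 libraries and the mat1Msmt0 libraries at 29C used the strand column, and the 31 libraries of the meiotic course used the column without strand (ratios of 2.19 to 7.47). Without strand, reads of a gene and of an overlapping gene on the other strand cannot be told apart and are dropped, so genes with such neighbours are uncertain in the course. Paralogs such as ribosomal protein pairs can share reads and are uncertain too.

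Gene reads per library, in units of 1e6, ran from 10.2 to 56.5 over the 46 libraries. They ran from 13.8 to 56.5 in the course, from 10.2 to 14.3 in the tor2-ts6 h90 set, from 25.5 to 41.8 in the GFP-Pir1 set and from 11.8 to 30.8 in the mat1Msmt0 set. Entries that name no gene were left out of totals and tests. Reads overlapping several genes made up 13.2 to 30.45% of a library, multimapping reads 2.98 to 14.69%, reads with no gene 0.69 to 1.91% and unmapped reads 0.25 to 3.9%. The 10 most abundant genes took 7.2 to 38.7% of gene reads. Reads are PCR products counted without molecular identifiers, so counting error understates the spread. Of 7015 feature IDs common to the tables, 6845 (97.6%) matched the reference gene table, which was used for names only, and 4409 had a symbol. The gene of Pir1 carries the symbol iss10 and the gene mcp5 the symbol num1.

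Tests were run in R 4.3.3 with edgeR 4.0.16 (TMM, filterByExpr, glmQLFit and glmQLFTest, Benjamini-Hochberg adjustment, threshold 0.05). Loss of Pir1 in vegetative cells was tested over 11 libraries with the strain background as a block, and in the tor2-ts6 deletion strains over 6 libraries in the same way. The ubiquitin-pathway deletions were compared with tor2-ts6 in a fit of 8 libraries, where tor2-ts6 has 1 library and is assumed to vary like the others. The course was fitted over 31 libraries with the time as a block and the strain as a term. With 1 library per strain and time, its p measures how steady a difference is over the course. Interactions of strain with phase were tested with an F test. Libraries are not stated to be separate cultures. For pairs of single libraries, the log2 ratio of scaled CPM with a prior count of 2 was taken, among genes with at least 50 reads in either library, and a gene counts as higher or lower at an absolute log2 ratio of 1 or more. Those pairs have no replicate check and no p. Their list medians were placed among 10000 random lists of equal size matched on mean expression.

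Gene lists were written before the data were examined, as were the tests, the alternatives and the naming rule. They cover Mmi1 targets, meiotic recombination and cohesion, horsetail movement, middle meiosis, spore wall, mating, nitrogen starvation, core stress, phosphate, iron, ribosomal proteins, ribosome biogenesis, the RNA elimination and exosome machinery, heterochromatin, the Cul4 ubiquitin ligase, S phase, and markers of M and P cells. They were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and again with an estimated correlation, adjusted over lists and comparisons. Genes named are the 8 largest rises and 8 largest falls past the threshold with a symbol, a mean of at least 20 reads and the same direction in every background or in at least 8 of the 10 times, up to 4 members of each list with the smallest p, and a fixed set of anchor genes. In pairs the rule asks for 100 reads in either library. A selection of these genes is printed.

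Alternatives were DESeq2 size factors, no filter, DESeq2 1.42.0, the other count columns, fits without a block, fits without each library, background or time, other prior counts, other read minimums and scaling to total counts. An adjusted p that DESeq2 gives as NA stayed NA (498 genes in the comparison of ubiquitin-pathway deletions). A library batch term and the stranded column in all course libraries were added after the data were examined, as were splits within a background or a time and the RNA elimination list without the deleted gene.

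The code was tested on simulated counts with 200 changed genes, 100 at a log2 change of 1 and 100 at 2. edgeR recovered 71 and 90% of them for loss of Pir1 in vegetative cells, 98 and 96% in the tor2-ts6 deletion strains, and 1 and 27% for the ubiquitin-pathway deletions (DESeq2 10 and 66%). In these comparisons, in that order, DESeq2 called 30, 20 and 31 unchanged genes, and edgeR 7, 16 and 0. The recovery of edgeR was 79 and 99% for red1 over the course, 75 and 97% for pir1 and 67 and 99% for red1 against pir1. For the course itself edgeR recovered 39 and 81% in starved cells, 58 and 87% at 1 to 3 h, 60 and 93% at 4 to 6 h, and 60 and 90% at 7 to 8 h. The phase test recovered 58% of 200 genes changed by 2, and the pairs 100%.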

Results

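RNA was sequenced from fission yeast cells in 46 libraries with gene counts. A set of 8 libraries compares h90 cells in rich YEA medium at 30C, namely wild type, the temperature-sensitive TORC1 kinase allele tor2-ts6, and tor2-ts6 with a deletion of ubi4, cul4 or ddb1, each with and without the RNA elimination factor Pir1. A course of 31 libraries follows pat1-as2 diploids, in which inhibition of the Pat1 kinase by 25 µM 1-NM-PP1 starts meiosis, from vegetative growth through nitrogen starvation to 8 h of meiosis. It holds 11 wild-type, 10 red1 deletion and 10 pir1 deletion libraries, with 1 library per strain and time except for 2 vegetative wild-type libraries. In 4 libraries cells express GFP-Pir1 or its SD or SA variant. Another 3 are mat1Msmt0 cells at 29C. Gene reads per library, in units of 1e6, ran from 10.2 to 56.5.

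The deleted genes were checked first. The Pir1 gene iss10 stood at 1.1 to 5.15 CPM (counts per 1e6 gene reads) in the pir1 deletion course (10 libraries), against 21.9 to 108 in wild type and 30.2 to 81.4 in the red1 deletion. In h90 cells it stood at 3.16, 15.7 and 5.7 where Pir1 was deleted beside ubi4, cul4 and ddb1, against 54.2 to 70.9 elsewhere, and in mat1Msmt0 cells at 0.721 and 1.09 against 63.2. The red1 gene stood at 2.74 to 13.1 in its deletion and at 83.8 to 176 in the wild-type course. The polyubiquitin gene ubi4 stood at 48.4 and 41.1 in its deletions against 226 to 375, and ddb1 at 7.7 and 8.0 against 128 to 242. Reads of cul4 depended on the count column. In the stranded column they stayed at 942 and 926 in the cul4 deletions, beside 686 in wild type. In the column without strand, which drops the part overlapping a feature on the other strand, they were 14 and 39, beside 613 to 899 in the other h90 libraries. The part seen only with strand held 928 and 887 reads, against 73 to 154 elsewhere.

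**Figure D1:**
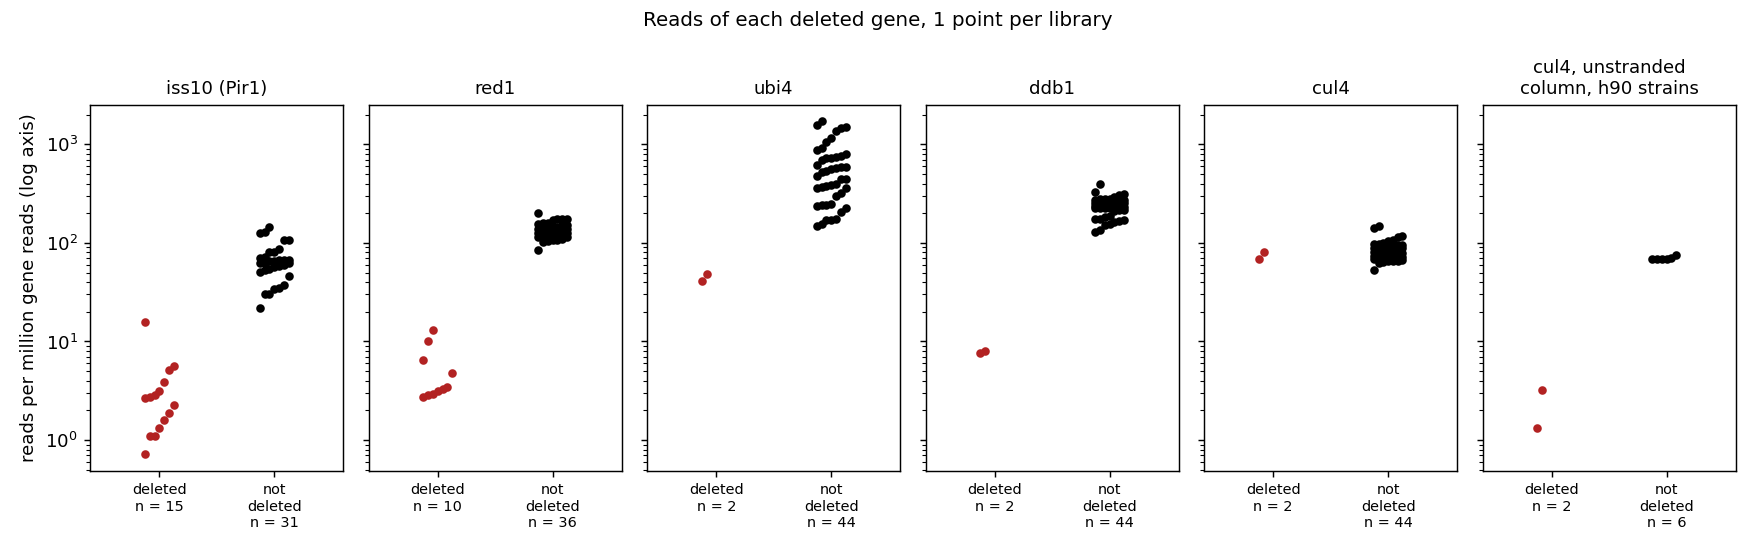
CPM of the deleted genes on a log axis, 1 point per library, for libraries in which the gene was deleted and all others. The last panel shows cul4 in the column without strand, where the deletion libraries stand at 1.34 and 3.19 and the others at 68.4 to 74.7.

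Loss of Pir1 in vegetative cells raised meiotic transcripts that Mmi1 marks for removal during growth. The 5 backgrounds are tor2-ts6 with a ubi4, cul4 or ddb1 deletion, mat1Msmt0 cells in EMM and the vegetative pat1-as2 diploid. In the tor2-ts6 strains, 6 of the 11 libraries, mei2 stood at 312 to 1210 CPM, against 14.1 in wild-type h90 cells. In 11 libraries of 5 backgrounds, mug10 rose by 2.30 ± 0.33 (log2, SE; adjusted p = 0.0427, edgeR quasi-likelihood, as for all tested values here), mug9 by 2.26 ± 0.32 (0.0427), mug8 by 2.15 ± 0.19 (0.0036) and the meiotic transcription factor gene mei4 by 1.39 ± 0.17 (0.0209). The autophagy gene atg1802 had the largest rise, 3.11 ± 0.19 (0.00145). Recombination genes rose too, with rec11 at 1.65 ± 0.14 (0.0036), mek1 at 1.56 ± 0.17 (0.00986), rec25 at 1.5 ± 0.10 (0.00145) and meu13 at 1.12 ± 0.13 (0.017). So did meu1 (1.81 ± 0.14, 0.00279), the dynactin gene arp1 (1.63 ± 0.24, 0.0433), rep1 (0.92 ± 0.09, 0.00682) and the ribosomal protein gene rpl3002 (0.97 ± 0.10, 0.00662). The deleted gene iss10 fell by 3.73 ± 0.51 (0.0385).

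Many Mmi1 targets were higher without passing over all genes. These include num1 (2.42 ± 0.38, adjusted p = 0.111), the cohesin gene rec8 (1.86 ± 0.35, 0.11), spo5 (1.79 ± 0.29, 0.0678) and ssm4 (1.40 ± 0.30, 0.191). The regulators mei2 (0.09 ± 0.19, 0.945) and ste11 (0.11 ± 0.16, 0.899) did not change by the edgeR test. The Mmi1 target mcp7 did not pass either (−0.44 ± 0.32, 0.833), but its direction differed between backgrounds. It lay above 0 in the tor2-ts6 strains and was lower in the mat1Msmt0 pair. Of 6438 genes tested, 26 rose and 1 fell. Of 15 Mmi1 targets, 4 rose (7 with the stranded column in all libraries), and 13 rose adjusted over the list alone (median 1.46). Of 19 recombination genes, 5 rose (10 adjusted over the list alone, median 0.81). Of 9 horsetail genes 0 did by edgeR (1 with the stranded column in all libraries, 6 adjusted over the list alone, median 0.87). By camera these lists stood above other genes (adjusted p = 2.15e-42, 1.28e-22 and 3.02e-12), which was lost with an estimated correlation (adjusted p = 0.119, 0.0901 and 0.172 with an estimated correlation). Middle meiosis (1 of 17 rose, median 0.11, 0.00143), spore wall (0 of 14, median 0.10, 0.019), nitrogen starvation (0 of 12, median 0.33, 0.0245) and ribosomal proteins (1 of 141, median −0.14, 0.000104) passed camera at the preset correlation only (adjusted p = 0.179, 0.434, 0.596 and 0.699 with an estimated correlation). Core stress (0.339), phosphate (0.167), iron (0.788), mating (0.498), ribosome biogenesis (0.429), RNA elimination and exosome (0.441), heterochromatin (0.418), the Cul4 ligase (0.308), S phase (0.107), M cells (0.124) and P cells (0.429) did not pass camera.

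The Pir1 call count fell when any background other than the diploid was left out, with fewer libraries in each such fit. Leaving out the ubi4 pair left 8 higher genes, the cul4 pair 11, the ddb1 pair 8 and the mat1Msmt0 pair 12, while leaving out vegetative wild-type library 1 gave 51 and the diploid pair 33. The genes atg1802, mug8, meu1, rec11, rec25 and rpl3002 passed in each of those fits, and mei4, mek1, mug10, mug9, meu13, rep1 and arp1 each fell short in some. The iss10 call fell short without ubi4 (−3.60, 0.197), without ddb1 (−3.80, 0.201), without the diploid (−3.65, 0.101) or without vegetative wild-type library 2 (−3.70, 0.0915), with fewer libraries and a fold close to that of all backgrounds. Leaving out vegetative wild-type library 2 gave 18 higher genes. That library is near the vegetative pir1 deletion diploid in reads counted as opposite-strand with no feature (1.2 and 1.39%). Library 1 is not (8.1%). DESeq2 called 87 higher and 8 lower genes.

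Within the tor2-ts6 deletion strains, whose 6 libraries are among the 11 above, the same kind of transcript responded to loss of Pir1. In 3 pairs, mug10 rose by 2.99 ± 0.24 (adjusted p = 0.0245, edgeR), atg1802 by 2.73 ± 0.09 (0.00396), the linear element gene rec27 by 2.64 ± 0.23 (0.0288), mug8 by 2.46 ± 0.19 (0.0224), ssm4 by 1.96 ± 0.21 (0.0459) and tht2 by 1.64 ± 0.11 (0.0208). Also higher were arp1 (2.16 ± 0.16, 0.0218), rec11 (1.95 ± 0.14, 0.0208), mek1 (1.90 ± 0.12, 0.0172), hop1 (1.63 ± 0.09, 0.0159), rec25 (1.40 ± 0.08, 0.0159) and jnm1 (0.97 ± 0.10, 0.0453). The mei4 rise of 1.70 ± 0.18 (0.0501), the rec8 rise of 2.54 ± 0.34 (0.0953) and the iss10 fall of 3.05 ± 0.47 (0.151) did not pass, and mei2 (−0.20 ± 0.17, 0.699) and ste11 (−0.04, 0.927) did not change by this test. Of 6331 genes, 27 rose and 0 fell by edgeR, with 487 at an unadjusted p under 0.05, and DESeq2 called 79 higher and 3 lower. Of 15 Mmi1 targets, 5 rose (14 adjusted over the list alone, median 1.96, camera 1.34e-56, adjusted p = 0.236 with an estimated correlation). Of 19 recombination genes, 6 rose (11 adjusted over the list alone, median 0.85, 5.18e-32, adjusted p = 0.178 with an estimated correlation). The mating list (median −0.45, 1.25e-05) and the M cell markers (median −0.86, 5.74e-07) were lower by camera, neither with an estimated correlation (0.606 and 0.564). Without the ddb1 pair no gene passed (445 at an unadjusted p under 0.05, lowest adjusted p 0.134), without ubi4 16 did, and without cul4 34 rose and 1 fell. Without cul4, iss10 passed (−3.85, 0.00294). The ubi4 pair also differed in ura4, at 45.7 CPM with Pir1 deleted and 0.706 with Pir1 present. The Pir1 effect in the tor2-ts6 strains against that in the other 2 backgrounds differed in no gene by edgeR (168 at an unadjusted p under 0.05, lowest adjusted p 0.117; no other tool was run).

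**Figure D2:**
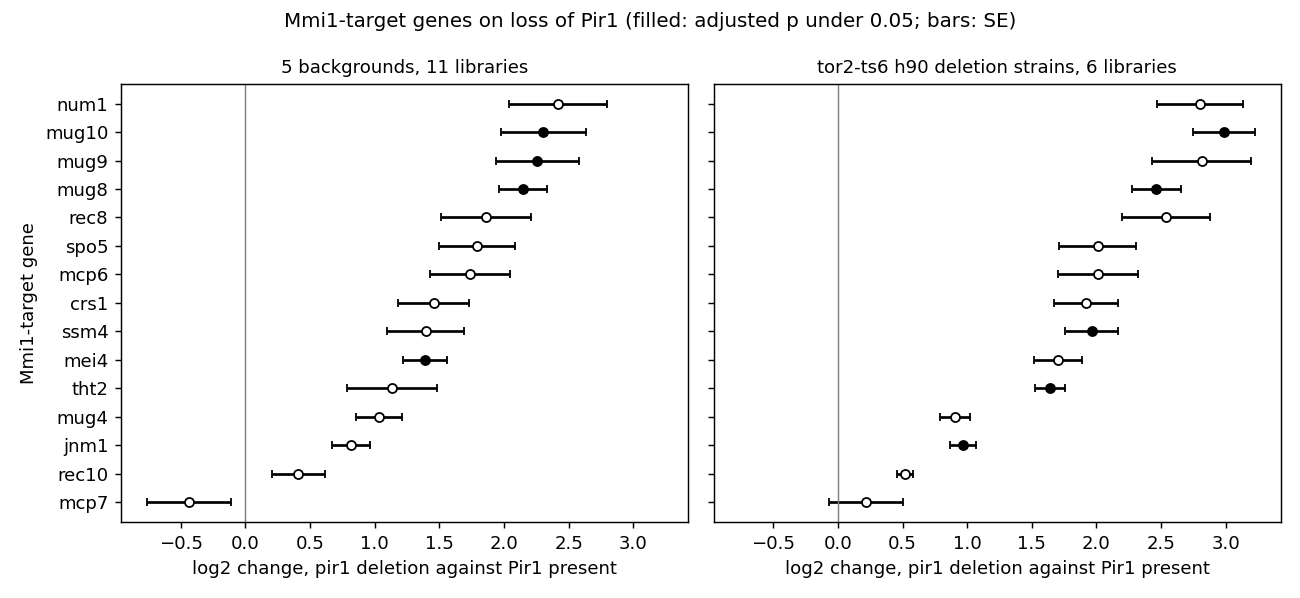
Log2 change of the Mmi1-target genes on loss of Pir1 in 5 vegetative backgrounds (11 libraries) and in the tor2-ts6 deletion strains alone (6 of those libraries). Points are shown with SE, filled where the adjusted p is under 0.05. In vegetative cells 14 of the 15 genes lie above 0, and in the tor2-ts6 strains all 15 do.

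The tor2-ts6 strain at 30C expressed mating and early meiotic genes that TORC1 holds down in wild type. Each strain has 1 library, so there is no replicate check. The strains also differed in ura4, at 0.0961 CPM in wild type and 35.7 in tor2-ts6, which was not separated from the tor2 allele. The M pheromone gene mfm1 was higher by 10.65 (log2), urg1 by 9.49, map2 by 8.84, mei2 by 7.61, spo5 by 6.63, ste11 by 4.94 and the protease gene isp6 by 4.33. Among Mmi1 targets, rec8 stood at 2.47, mei4 at 1.48, ssm4 at 0.26 and mcp7 at −0.52, while iss10 (−0.11) and tor2 (0.93) stayed under the size rule. Among the genes lower in tor2-ts6 were the ribosomal genes rps1202 at −3.43 and rpp203 at −2.98 and the glycolytic genes gpm1 at −2.89 and pgk1 at −2.88. Of 5642 genes, 976 were higher and 803 lower. The lists moved together, with 21 of 22 mating genes higher (median 5.09), 18 of 19 recombination genes (2.67), 14 of 14 spore wall genes (1.83), 11 of 15 Mmi1 targets (1.92) and 8 of 12 nitrogen starvation genes with 1 lower (3.1), each median at percentile 100 of random lists. Of 141 ribosomal protein genes, 137 were lower (median −2.24, percentile 0), as were 12 of 25 ribosome biogenesis genes (median −0.98). Scaling to total counts moved the median of all genes by 0.39, and these directions are relative to TMM scaling.

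In the authors' own comparisons of mat1Msmt0 cells at 30C, mating and ribosomal protein genes lie in the directions seen in h90 cells. For tor2-ts6 their table gives mfm1 7.38, mei2 6.25, ste11 3.97 and iss10 1.24, and rps1202 at −3.02. It places 17 of 22 mating genes at a log2 fold of at least 1 and 1 at −1 or lower (median 2.84), 11 of 15 Mmi1 targets (1.35) and 129 of 141 ribosomal protein genes at −1 or lower (median −2.18). Of 12 nitrogen starvation genes 10 were at 1 or more and 1 at −1 or lower (median 4.38), and 19 of 25 ribosome biogenesis genes at −1 or lower (−1.21). Recombination genes were split, 7 of 19 at 1 or more and 2 at −1 or lower (median 0.77), as were the P cell markers (1 and 1 of 4, median 0.38), and the phosphate median was 2.40, against 0.10 in h90 cells. For the pir1 deletion it gives atg1802 4.12, mei4 2.10, mei2 −0.03, mcp7 −2.04 and iss10 −6.95, with 12 of 15 Mmi1 targets at 1 or more and 1 at −1 or lower (median 1.62). At the authors' q-value under 0.05 and an absolute log2 fold of 1 or more, 1506 genes were higher and 839 lower of 6495 for tor2-ts6, and 434 higher and 84 lower of 6493 for the pir1 deletion.

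The mating and meiotic genes of tor2-ts6 stood lower where ubi4, cul4 or ddb1 was deleted as well. Each strain has 1 library and no replicate check. The ubi4 deletion also differed from tor2-ts6 in ura4, at 0.706 against 35.7 CPM. Against tor2-ts6, mei2 stood at −1.30 in the ubi4 deletion, −2.91 in the cul4 deletion and −1.48 in the ddb1 deletion, ste11 at −1.03, −1.86 and −0.96, and spo5 at −3.80, −4.32 and −3.44. In CPM, mei2 stood at 14.1 in wild type, 2700 in tor2-ts6, 1070 in the ubi4, 351 in the cul4 and 959 in the ddb1 deletion, so it stayed above wild type. The mating list was lower in 14, 19 and 18 of 22 genes (medians −1.16, −2.23 and −1.42) and the Mmi1 targets in 9, 7 and 5 of 15 (medians −1.31, −0.86 and −0.76), all at percentile 0. The largest single falls were ptr2 (−6.67) and meu17 (−4.59) with ubi4, isp4 (−6.37), urg1 (−4.91) and mfm3 (−4.77) with cul4, and meu17 (−4.94) with ddb1. The subtelomeric gene tlh2 was higher by 6.36 with cul4, and the heat shock gene hsp16 by 4.82 with cul4 and 3.99 with ddb1. Counts of higher and lower genes were 88 and 445 for ubi4, 529 and 345 for cul4, and 300 and 137 for ddb1.

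Tested as 3 deletions against the lone tor2-ts6 library, no gene passed. By edgeR 0 of 6404 genes rose or fell, with 252 at an unadjusted p under 0.05 and a lowest adjusted p of 0.219, while DESeq2 called 5 higher and 55 lower. The leading genes were meu17 (−4.29 ± 0.59), spo5 (−3.83 ± 0.45), meu10 (−3.46 ± 0.38), mug4 (−2.33 ± 0.32) and mik1 (−1.32 ± 0.18), all at 0.219. For mei2 (−1.76 ± 0.77, 0.991) and ste11 (−1.25 ± 0.52, 0.991) the deletions differed among themselves. By camera the recombination list was lower (median −1.49, 1.11e-21, adjusted p = 0.172 with an estimated correlation, 7 of 19 adjusted over the list alone), as were mating (−1.54, 3.31e-18, 0.348, 2 of 22), spore wall (−0.76, 1.95e-18, 0.0901, 8 of 14) and Mmi1 targets (−0.91, 7.96e-14, 0.348, 4 of 15). The middle meiosis list stood at −0.91 (6.76e-20, adjusted p = 0.047 with an estimated correlation, 8 of 17 adjusted over the list alone). A shift of the lone tor2-ts6 library would move these lists together, so their p does not tie the difference to the deletions. Ribosomal protein genes stood higher (median 0.44, 1.06e-17, 0.596). The S phase list has a median of 0.15 and a mean of 0.02 while camera points down (0.815).

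With Pir1 deleted as well, the Mmi1-target median stood above tor2-ts6, with members on both sides, and the mating median stayed below it. Of 15 Mmi1 targets, 2 were higher and 2 lower than in tor2-ts6 with ubi4 (median 0.26), 9 and 2 with cul4 (1.06), and 8 and 2 with ddb1 (1.29). The mating medians were −1.05, −2.98 and −2.10. Cohesin gene rec8 stood at 0.13, 1.37 and 1.48, spo5 at −2.57, −1.5 and −1.5, and iss10 at −4.22, −1.99 and −3.44. Against wild type the Mmi1-target medians were 1.01 without and 2.49 with Pir1 loss in ubi4, 0.62 and 3.05 in cul4, and 1.23 and 3.40 in ddb1. These values have no replicate check. Scaling to total counts moved the median of all genes against wild type by 0.29 and 0.31 for ubi4 without and with Pir1 loss, 0.59 and 0.55 for cul4, and 0.48 and 0.48 for ddb1, and against tor2-ts6 by 0.16 for cul4.

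Meiotic genes stood lower with the SD variant of GFP-Pir1 than with GFP-Pir1 in EMM at 18C, and close to GFP-Pir1 with the SA variant. With SD, rem1 was lower by a log2 ratio of −3.26, mde2 by −3.03, spo5 by −2.95, dmc1 by −2.63 and mde3 by −2.58, and rec8 stood at −1.41, mei4 at −0.62 and mei2 at −0.18. With SA, rec8 stood at −0.65, spo5 at −0.30 and mei4 at −0.05. The gene iss10, which these strains express as GFP-Pir1, stood at 0.17 with SD and −0.04 with SA. Of 19 recombination genes, 14 were lower with SD (median −1.41), as were 9 of 15 Mmi1 targets (−1.10), 9 of 17 middle meiosis genes (−1.30) and 7 of 14 spore wall genes (−1), all at percentile 0, while ste11 stood at 0.33 and the mating median at 0.12. No gene of these lists passed the size rule with SA, where the Mmi1-target median of −0.11 was at percentile 0. Both variants had shu1 (2.97 and 2.20) and eno102 (2.07 and 1.99) higher, against the same GFP-Pir1 library. A low value in that library alone would give the same. SA had the copper transporter genes ctr4 (−1.59) and ctr5 (−1.16) lower. Of 5899 genes, 23 were higher and 211 lower with SD, and of 5934, 17 were higher and 31 lower with SA. Against SA, the SD library had 3 genes higher and 173 lower of 5894, the former being the iron genes str3 (1.46), fio1 (1.29) and fip1 (1.10), and mde2 (−3.07), rem1 (−2.85), spo5 (−2.65) and dmc1 (−2.62) lower. Each variant has 1 library and no replicate check.

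Between media and temperatures, which differ together, the meiotic genes of GFP-Pir1 cells lay further apart than between the variants, again from single libraries with no replicate check. In EMM at 18C against YEA at 30C, the thiamine-repressed gene nmt1 was higher by 12.06, meu3 by 9.28, isp3 by 8.11, spo5 by 7.24, rec8 by 3.50, mei2 by 2.59 and mei4 by 1.88, while mcp7 stood at −2.50, fub2 at −4.97, yhb1 at −3.87, ste11 at 0.23 and iss10 at 0.26. Of 15 Mmi1 targets 14 were higher and 1 lower (median 2.06), and 122 of 141 ribosomal protein genes were lower (median −1.32), with 709 genes higher and 486 lower of 5951. In mat1Msmt0 cells in EMM at 29C, the pir1 deletion had atg1802 higher by 3.43, mug10 by 1.81, mug8 by 1.61, rec25 by 1.54, spo5 by 1.54 and mei4 by 1.07, with mcp7 at −1.34, isp4 at −1.72, wwm3 at −2.43 and iss10 at −5.78. There 9 of 15 Mmi1 targets were higher and 1 lower (median 1.05, percentile 100), among 54 genes higher and 38 lower of 5825. In pir1 deletion cells, EMM against YEA at 29C had nmt1 higher by 14.23, mfm1 by 7.97, mei2 by 5.84 and ste11 by 3.68, with gdt1 at −2.38, while mei4 (0.03), ssm4 (0.28) and iss10 (0.52) stayed under the size rule. There 14 of 21 mating genes were higher (median 2.64), among 301 genes higher and 114 lower of 5790. Scaling to total counts moved the median of all genes by 0.18 for the GFP-Pir1 media and 0.19 for the pir1 deletion media.

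Across the 3 diploid strains mating and spore wall genes were higher than in vegetative cells already on starvation, and no test compared the later phases with each other. In starved against vegetative cells, mfm1 rose by 5.52 ± 0.68 (adjusted p = 9.38e-07, edgeR), mei2 by 4.24 ± 0.48 (2.73e-07), mam3 by 4.14 ± 0.35 (3.34e-09), isp6 by 3.96 ± 0.33 (2.77e-09) and ste11 by 2.32 ± 0.42 (0.000122), and rps1502 fell by 5.22 ± 0.46 (6.54e-09). Of 20 mating genes 19 rose (median 2.78, camera 2.43e-12, adjusted p = 0.181 with an estimated correlation), as did all 6 M cell markers (4.08, 3.93e-06, adjusted p = 0.236 with an estimated correlation), 3 of 4 P cell markers (1.45, 0.121) and 7 of 10 spore wall genes (2.10, 0.00506, adjusted p = 0.563 with an estimated correlation). Of 116 ribosomal protein genes 113 fell (−3.91, 2.38e-111, adjusted p = 0.047 with an estimated correlation). At 1 to 3 h, spo5 stood 7.02 ± 0.97 above vegetative cells (2.69e-06), isp3 6.32 ± 0.75 (2.97e-07) and mei4 2.77 ± 0.67 (0.00142), and put4 fell by 4.56 ± 0.55 (3.8e-07). Of 12 nitrogen starvation genes, 2 rose and 7 fell (median −1.10, 0.0302, adjusted p = 0.488 with an estimated correlation). At 4 to 6 h all 11 middle meiosis genes (median 3.86, 0.000738, adjusted p = 0.574 with an estimated correlation) and all 10 spore wall genes (5.28, 5.79e-06, adjusted p = 0.261 with an estimated correlation) had risen, among them agn2 by 6.11 ± 0.75 (3.95e-07). S phase genes fell, 9 of 14 with 2 higher (median −1.31, 0.0308, adjusted p = 0.606 with an estimated correlation), tos4 and cdt1 also falling (−3.80 with 3.47e-08 and −2.91 with 3.09e-08). The heterochromatin gene swi6 (−0.96, 7.24e-07) and mmi1 (−0.65, 6.4e-05) fell and ubi4 rose (2.20, 7.22e-07). At 7 to 8 h isp3 reached 10.09 ± 0.89 (6.1e-09), hsp16 4.51 ± 0.62 (2.65e-06) and the siderophore gene str2 3.23 (1.7e-06), with 7 of 10 iron genes higher and 1 lower (median 0.96, 0.0238, adjusted p = 0.574 with an estimated correlation). Phosphate genes fell in 3 of 5 (−1.68, 0.0666), with pho4 at −1.87 (7.23e-09). Counts of higher and lower genes of 5687 were 1155 and 1101 in starved cells, 1523 and 1557, 1761 and 1835, and 1538 and 1604 in the later phases. Without the pir1 deletion strain the starved counts were 529 and 685, and without wild type the 1 to 3 h count of higher genes was 995, mei4 then falling short (2.01, 0.0832).

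Loss of Red1 raised Mmi1 targets over the course. Over 10 times, mug8 rose by 2.09 ± 0.29 (adjusted p = 1.01e-05, edgeR), rec8 by 2.08 ± 0.41 (0.00044), spo5 by 1.75 ± 0.52 (0.0128), ssm4 by 1.09 ± 0.27 (0.00373) and the shugoshin gene sgo1 by 3.31 ± 0.33 (1.13e-07), while red1 itself fell by 4.74 ± 0.20 (3.27e-14). The mei4 rise of 1.11 ± 0.44 (0.054), mei2 (0.51, 0.149) and ste11 (0.50, 0.125) did not pass, and spo5 fell short without the vegetative time (1.25, 0.0698). Of 12 Mmi1 targets 10 rose (11 higher and 1 lower adjusted over the list alone, median 1.22, camera 0.000139, adjusted p = 0.434 with an estimated correlation), as did 8 of 12 recombination genes (10 adjusted over the list alone, median 0.98, 0.000173, adjusted p = 0.408 with an estimated correlation). Ribosomal protein genes fell, 68 of 116 (73 adjusted over the list alone, median −0.57, 2.99e-11, adjusted p = 0.596 with an estimated correlation), with rpl3202 at −1.27 ± 0.14 (6.47e-07). Of 15 RNA elimination and exosome genes other than red1, 3 rose and 4 fell (median −0.07), csl4 among the latter (−0.63 ± 0.09, 2.47e-05). Without red1 the list did not pass camera (0.479), and its call with red1 (0.0259) rested on the deleted gene. Among heterochromatin genes 4 of 15 rose and 1 fell, rdp1 being among the former (0.57 ± 0.10, 0.000137). In the stranded column 2 of 16 rose and 1 fell (median 0.03). Iron genes moved both ways, str3 (1.55 ± 0.29, 0.000315) and fio1 (1.15 ± 0.22, 0.000345) up and the repressor gene fep1 (−0.34, 0.00724) down. Core stress rose in 5 of 16 genes (median 0.47, 0.0827). In the Cul4 ligase list rbx1 fell (−0.89 ± 0.10, 5.09e-07), with 1 of 6 genes higher and 2 lower. The spore wall list has a median of 0.06 and a mean of −0.08 (camera down, 0.835), with agn2 lower (−1.32 ± 0.40, 0.0141). Of 5687 genes, 807 rose and 1028 fell. The p measures steadiness over times that share strains, not separate cultures.

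Large Red1 differences lay in a chromosome II block from nrg1 to the galactose gene gal1, whose reads were near 0 in the wild-type diploid. The non-coding RNA nam3 (8.36 ± 0.40, 2.43e-13) and the genes gal1 (7.19 ± 0.34), gal10 (6.85 ± 0.33), gal7 (6.78 ± 0.37, 2.88e-12), pan5 (6.63 ± 0.24, 3.01e-15) and nrg1 (5.36 ± 0.41, 1.1e-09) were higher by edgeR in the red1 deletion. In the pir1 deletion nam3 (7.45 ± 0.39, 2.3e-12), say1 (6.70 ± 0.27, 1.53e-14), pan5 (6.22 ± 0.24, 8.9e-15) and gal1 (4.12 ± 0.33, 4.7e-09) were higher. With the library batch as a term nam3 (0.0161), say1 (0.000927) and pan5 (0.000386) still passed in the pir1 deletion, and gal1 did not (5.04 ± 1.32, 0.371). In the 11 wild-type libraries nam3 stood at 0.0767 to 4.88 CPM, against 52.6 to 246 in the red1 and 41.8 to 129 in the pir1 deletion. Wild types of other strains expressed the block, with medians over 11 genes of 20.4 CPM in h90 and 35.3 in mat1Msmt0 cells. Wild-type h90 cells expressing GFP-Pir1 stood lower, at 3.27 in YEA and 17.5 in EMM. Differences of the block from the wild-type diploid may therefore reflect that strain or the deletions, which was not settled here. Libraries with red1 deleted exist only in the diploid, so Red1 loss cannot be told apart from that strain. The RNA nam3 was also higher in each Pir1 pair outside the diploid (0.69, 0.99, 0.87 and 1.19, single libraries), though by less than in the diploid. For nam3, wild-type h90 cells stood at 4.32 and wild-type mat1Msmt0 cells at 19.9 CPM, against a median of 0.243 in the wild-type diploid, whose highest value of 4.88 is its 1 h library.

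The pir1 deletion course cannot be told apart from a library batch. Its 10 libraries and the second vegetative wild-type library had 1.2 to 2.72% of reads counted as opposite-strand with no feature, against 8.1 to 10.71% in the other wild-type and all red1 deletion libraries. That is not a share of reads outside genes, since reads with no gene made up 0.69 to 1.85% in the course. As fitted, iss10 fell by 4.39 ± 0.28 (adjusted p = 1.13e-10, edgeR), and the late genes isp3 (2.90 ± 0.41, 6.77e-06) and agn2 (1.77 ± 0.42, 0.00171) and the Mmi1 targets mei4 (1.48 ± 0.44, 0.00893) and crs1 (1.04 ± 0.30, 0.00757) rose. The recombination gene hop1 fell (−2.45 ± 0.55, 0.000954), a call that ended in the stranded column (0.07, 0.904), and the ammonium transporter gene amt1 rose (1.28 ± 0.20, 1.75e-05). Neither ssm4 (0.09, 0.821), rec8 (0.68, 0.173), spo5 (0.98, 0.129) nor mei2 (−0.03, 0.931) passed. Without the 1 h time rec8 passed (1.02, 0.025), and without the 3 h time spo5 did (1.32, 0.0443). Of 116 ribosomal protein genes 74 rose and 8 fell (77 and 9 adjusted over the list alone, median 0.62, camera 3.63e-13, adjusted p = 0.564 with an estimated correlation), of 12 nitrogen starvation genes 8 rose and 1 fell (0.63, 0.00601, 0.348 with an estimated correlation), and of 10 spore wall genes 6 rose (1.12, 0.0155, 0.596 with an estimated correlation). Of 15 RNA elimination and exosome genes other than iss10, 5 fell (median −0.23), among them rrp6 (−0.66, 2.19e-06). Without iss10 the list did not pass camera (0.0675), and its call with iss10 (0.00506) rested on the deleted gene. Of 12 Mmi1 targets 3 rose and 1 fell (0.56, 0.182). The recombination list has a median of 0.09 and a mean of −0.11 with camera up (0.763). In all, 987 genes rose and 1373 fell. With the batch as a term 3 rose and 3 fell, and that term rests on the single wild-type library of the batch. The gene iss10 still passed (−4.21 ± 0.58, 0.000915). For isp3 (4.14 ± 1.28, 0.771), mei4 (2.34 ± 1.31), rec8 (2.20 ± 1.15), spo5 (3.50 ± 1.55) and ssm4 (1.67 ± 0.75) the change was larger than without the term, and so was its error. With that term the ribosomal protein median turned to −0.30 and the nitrogen starvation median dropped to 0.14, with 0 genes of either passing by edgeR, while the Mmi1-target median was 1.98 and the recombination median 1.43, also with 0 passing. Of single genes, amt1 (0.16 ± 0.45) and hop1 (−0.57 ± 2.50) lay nearer to 0.

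Set against each other, the deletions differed in 1537 genes higher and 1350 lower in red1, with the same batch limit. The Mmi1 targets mug8 (1.51 ± 0.29, 0.000144, edgeR), rec8 (1.40 ± 0.40, 0.00525) and ssm4 (1.01 ± 0.28, 0.00442) and the recombination genes hop1 (3.73 ± 0.54, 5.03e-06) and rec10 (1.40 ± 0.30, 0.000494) were higher in red1, and isp3 (−3.59 ± 0.44, 6.63e-07) and rpl2002 (−3.76 ± 0.35, 1.28e-08) were lower. Of 12 recombination genes 10 were higher (median 1.16, 0.0238, 0.596 with an estimated correlation), and of 116 ribosomal protein genes 98 were lower and 4 higher (−1.22, 1.31e-28, 0.348 with an estimated correlation). With the batch as a term 18 genes were higher and 10 lower, and rec8 (−0.27), mug8 (−0.18), ssm4 (−0.70) and rec10 (−0.69) turned in direction without passing, while hop1 (1.76) and isp3 (−4.94) did not turn. The recombination median turned to −0.62 and the Mmi1-target median to −0.61, and the ribosomal protein median shrank to −0.21, with 0 genes of these lists passing by edgeR. In the stranded column hop1 did not pass (0.66, 0.227). Both deletions share the wild-type libraries. Across 5687 genes, which are not independent replicates, their changes correlated at 0.152 (covariance 0.093), against 0.474 (covariance 0.026) in 20 simulations of unchanged strains, a covariance difference of 0.067. They shared 168 higher and 346 lower genes, against 140.1 and 248.2 for independent lists, and 328 genes went opposite ways (373.2 for independent lists). The simulations gave 0 shared genes, but they hold no strain effect, so hardly any gene can pass there. That 0 is no reference for the overlap. With the wild-type libraries split between the deletions, the correlation was 0.089 or 0.185 and the covariance 0.06 or 0.112, with 26 or 14 genes higher in both (9.3 and 1.4 for independent lists) and 13 or 8 lower (6.5 and 1.4).

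By phase, the Red1 effect on Mmi1 targets was present before induction, not detected at 1 to 3 h, and present later. Before induction 11 of 12 rose (median 2.34), with rec8 at 3.26 (adjusted p = 0.00378, edgeR) and spo5 at 3.88 ± 0.72 (0.00347). At 1 to 3 h 0 rose by edgeR (median −0.11), with spo5 at −0.56 (0.616), and at 4 to 6 h 8 rose (1.43), with rec8 at 2.86 (0.00146) and spo5 at 2.26 (0.0168). At 7 to 8 h 5 rose (1.65). Only spo5 passed the phase interaction test among them (0.0314), so for the other targets a difference between phases was not shown. Ribosomal protein genes fell in 59, 3, 6 and 43 of 116, and the phase interaction passed for 5 of them, so a difference between phases was not shown for the rest. In the pir1 deletion, with its batch limit, 4 of 12 Mmi1 targets fell and 1 rose at 1 to 3 h (median −0.62), ssm4 by −1.27 (0.00972, interaction 0.038), and 7 of 12 recombination genes fell and 1 rose (−1.29), including mek1 (−1.80, 0.00777, interaction 0.0488). In the other phases the medians were above 0, at 0.70, 0.78 and 1.02 for Mmi1 targets (1, 3 and 1 higher) and 0.52, 0.65 and 0.54 for recombination genes (0, 2 and 0 higher), and the interaction passed for 2 of 12 genes in each list. Of 10 spore wall genes 7 rose at 1 to 3 h (2.14), agn2 by 3.65 (interaction 0.0266), as did 7 of 11 middle meiosis genes (1.80). The interaction passed for 497 of 5721 genes in red1 and 447 in pir1. Strains were compared at the same hour, and peaks lay at different hours. The gene mei4 was highest at 4 h in wild type (916 CPM), at 1 h in the pir1 deletion (789) and at 5 h in the red1 deletion (427), from single libraries. A change in level is therefore not told apart from a change in timing.

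**Figure D3:**
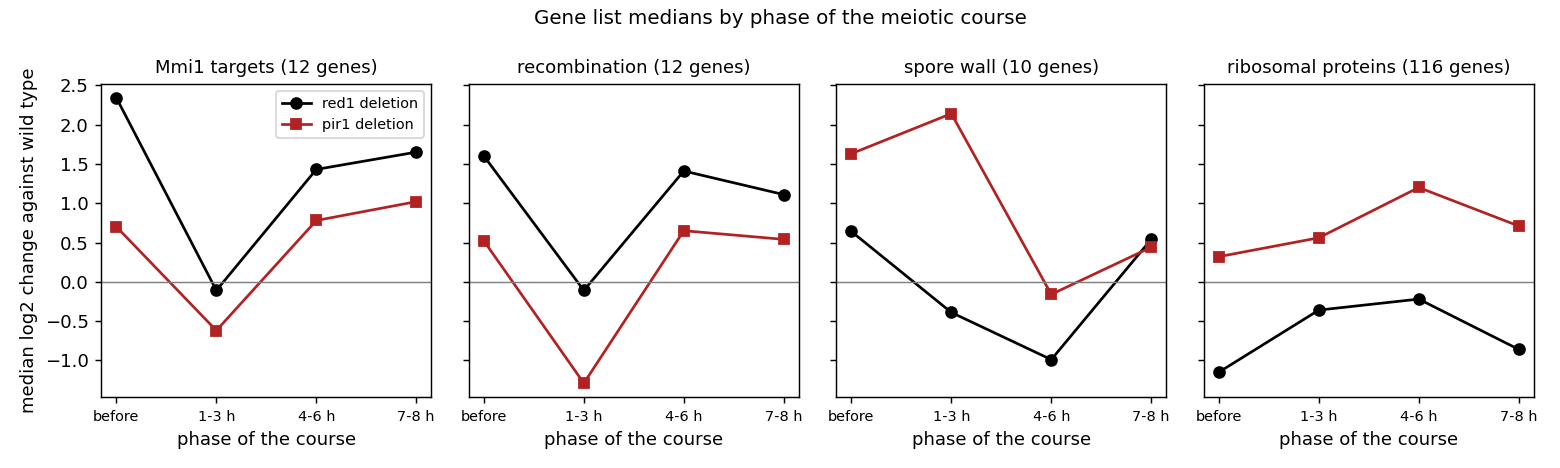
Median log2 change against wild type of Mmi1 targets, recombination, spore wall and ribosomal protein genes by phase, for the red1 deletion and the pir1 deletion. The Mmi1-target median of red1 is 2.34 before induction and −0.11 at 1 to 3 h, and the pir1 values carry the library batch.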

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

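The tests on the galactose genes, on cul4 and on the library batch behind the ribosomal protein genes were chosen only after the result was seen, while the test of Pir1 loss on ribosomal protein genes in other strains was written before.

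The effect of each deletion differed between phases of the course by the interaction test, in 497 of 5721 genes for red1 and in 447 for pir1, which is a difference between time groups. A difference in meiotic timing between the strains was not told apart from it. Examples are spo5 in red1 (adjusted p = 0.0314, edgeR quasi-likelihood) and ssm4 and agn2 in pir1 (0.038 and 0.0266). In data that no comparison used, reads on the opposite strand of genes made up 15.9% of gene reads in the tor2-ts6 library lacking cul4 and Pir1, against 12% in wild-type h90 cells.

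A block of 11 features on chromosome II was near 0 in the wild-type diploid, and its median was higher in both deletion diploids. It holds nrg1, pan5, gal1, gal7, gal10 and the non-coding RNA nam3. Not all of them were expressed alike in both deletions. The gene gal10 stood at 0.142 to 1.17 CPM in the pir1 deletion, near the 0 to 0.207 of wild type, against 1.7 to 21.6 in the red1 deletion. A library batch is excluded, since the block in the vegetative wild-type library of the pir1 deletion batch stood at 1.88% of the vegetative pir1 deletion library. Loss of Pir1 in other strains did not raise the block as a whole, with a median log2 change of −0.09 over 4 pairs (−0.11, −0.17, −0.01 and −0.07), although nam3 was higher in each (0.69, 0.99, 0.87 and 1.19, median 0.93, far below its 7.45 in the diploid) and nrg1 (3.30) and 3 other genes of the block, chosen after their values were seen (SPBPB2B2.05 at 1.34, SPBPB2B2.07c at 1.27, SPBPB2B2.08 at 1.43) in the cul4 pair, as was SPBPB2B2.07c in the ddb1 pair (1.07). A wild-type h90 library in YEA and a wild-type mat1Msmt0 library in EMM expressed the block at 66.5 times or more the wild-type diploid median. Wild-type h90 cells expressing GFP-Pir1 stood lower, at 3.27 CPM in YEA and 17.5 in EMM, against 0.0767 to 0.982 in the wild-type diploid libraries. The higher levels outside the diploid fit a strain difference of that diploid, with no sequence examined. The RNA nam3 stood at 4.32 CPM in wild-type h90 and 19.9 in wild-type mat1Msmt0 cells, against a median of 0.243 in the wild-type diploid.

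Ribosomal protein genes were higher in the pir1 deletion course than in wild type. A rise like the course median of 0.62 was not seen in 4 pairs in other strains, with a list median of −0.25 (−0.34, −0.30, 0.09 and −0.20). That value met the bound written beforehand against Pir1 loss as a cause that acts in every strain. The pairs are single libraries, all but the mat1Msmt0 pair in tor2-ts6 strains, and the authors' table for mat1Msmt0 cells at 30C gives 0.23. They cannot exclude that cause. The batch cannot be told apart from the deletion, because a single wild-type library shares it, and with the batch as a term the list median turned to −0.30, with 0 of 116 genes passing by edgeR. That wild-type library stood 0.94 above the other vegetative wild type in the list median, with 102 of 116 genes higher, and the vegetative pir1 deletion stood at −0.20 against it. By phase, 0 of 116 genes rose and 2 fell before induction (median 0.32) by edgeR. At 1 to 3 h 50 rose and 8 fell (0.56), at 4 to 6 h 78 and 2 (1.20), and at 7 to 8 h 39 and 3 (0.71). The phase interaction passed for 1 of the 116, so a difference between phases was not shown for the rest. With the batch limit, a change that Pir1 loss makes only during meiosis stays open.

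Reads of cul4 stayed at the wild-type level in the stranded column of the cul4 deletions, while in the column without strand the higher of them held 4.66% of the lowest other h90 library, so the reads lie in the part overlapping a feature on the other strand. A part left outside the deletion at its usual level is excluded, since its share of reads was at least 5.40 times that of any other h90 library (928 and 887 reads against 73 to 154). Libraries of tor2-ts6 without a further deletion are excluded, since cul4 stood at −4.48 (log2) or lower against tor2-ts6 there in both. Deletion of another gene in place of cul4 is excluded as well, since 1 gene fell under 10% of every other h90 library in both, and it was cul4, although the same search found 3 other genes and not ubi4 in the ubi4 deletions and 0 in the ddb1 deletions. What raises reads in that part stays open.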

How the results depend on the processing

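The library batch term, and the stranded column in all course libraries, were chosen after the data were examined. Of the values for named genes, 3140 were counted as the same, 138 no longer passed, 56 newly passed, 8 moved and 22 reversed. A tested value that changed direction counts as reversed only where either fit passed, and otherwise as the same. In pairs, a small move of the log2 ratio counts as the same. Of counts of genes, 409 stayed within 1.5 times and 79 did not. Of counts of list members, 4071 stayed within 1.5 times and 537 did not. These tallies include the column without strand for the course, which already uses that column. Agreement there was fixed in advance and adds to the values that stayed. Of the list tests, 67 passed at the preset correlation and 2 with an estimated one. Genes without reads in the column without strand have no value there. Depth limits genes with few reads, as the read minimums for the pairs show.

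With the library batch as a term, counts of higher and lower genes were 3 and 3 for pir1 (987 and 1373) and 18 and 10 for red1 against pir1 (1537 and 1350), the batch being confounded with the strain. For pir1 these genes reversed, with values of 0.14 for rbx1, 0.73 for meu26, 3.20 for mal2, −0.10 for pho4, −0.18 for rpl1601, −0.29 for isp4, −0.17 for rpl1701, 4.92 for stc1, −0.35 for gpd1 and −0.12 for fil1. For red1 against pir1 these did, with −0.18 for mug8, −1.49 for bqt1, −0.69 for rec10, −0.70 for ssm4, −1.16 for sgo1, −0.27 for rec8, −4.30 for stc1 and 0.00 for amt1. In the stranded column clr4 (−0.95) and dis1 (0.02) reversed for red1, and meu26 (0.32) and hop1 (0.07) for pir1, where overlapping features on the other strand are kept. Over all genes that column gave 824 and 1084 for red1, with 20 reversed, and 1458 and 1723 for pir1, with 118 reversed.

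DESeq2 gave 87 higher and 8 lower genes for Pir1 loss in vegetative cells (26 and 1), 79 and 3 in the tor2-ts6 strains (27 and 0) and 5 and 55 for the ubiquitin-pathway deletions (0 and 0), and the cause was not tested. On simulated counts DESeq2 also called more unchanged genes than edgeR in these comparisons (30, 20 and 31 against 7, 16 and 0). Without a block for the strain background, 1 and 0 genes passed in vegetative cells and 1 in the tor2-ts6 strains. Without a time block the counts were 309 and 560 for red1 (807 and 1028), 303 higher for pir1, and 986 and 771 for red1 against pir1, the variation between times then entering the error. Leaving out a background or library, higher genes ran from 8 to 51 and lower genes from 0 to 1 in vegetative cells, and from 0 to 34 and from 0 to 1 in the tor2-ts6 strains. Leaving out a strain, 529 to 991 genes rose and 685 to 901 fell in starved cells (1155 and 1101), lowest without the pir1 deletion, and 942 to 1514 rose at 1 to 3 h (1523), with 995 without wild type, from fewer libraries.

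Scaling to total counts gave 1528 higher and 441 lower genes for tor2-ts6 against wild type (976 and 803), and against wild type 963 and 358 for ubi4, 1116 and 417 for ubi4 with pir1, 1811 and 237 for cul4, 1956 and 320 for cul4 with pir1, 1710 and 347 for ddb1, and 1724 and 360 for ddb1 with pir1. The column without strand gave 15 and 137 for SD (23 and 211), 10 higher for SA (17), 86 lower for SD against SA (173) and 69 lower for the pir1 deletion media (114). It gave 610 higher for cul4 against wild type (949), and against tor2-ts6 57 and 246 for ubi4, 53 and 225 for ubi4 with pir1, 264 higher for cul4, 404 higher for cul4 with pir1, 146 and 71 for ddb1, and 239 and 87 for ddb1 with pir1. A minimum of 20 reads gave 73 lower for SA, 5 higher for SD against SA and 79 lower for pir1 deletion against wild type at 29C (38). A minimum of 200 gave 3 lower for SA, 23 lower for that pir1 pair, 52 lower for the pir1 deletion media, 266 lower for ubi4 and 246 lower for ubi4 with pir1 against tor2-ts6. It gave 577 higher for cul4 and 802 for cul4 with pir1 against wild type, and 245 for cul4, 355 for cul4 with pir1, 139 for ddb1 and 206 for ddb1 with pir1 against tor2-ts6, fewer genes being tested.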

Other observations

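The tests of the cul4 and ddb1 deletions and of other splits were written before the result was seen. The splits within a background or a time and the weighing of the cul4 and ddb1 value against another reference strain were chosen only after the result was seen.

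Recombination and horsetail genes rose early in the course of the 3 diploid strains, and no test compared the phases with each other. In starved cells mug20 rose by 4.02 (adjusted p = 3.6e-07, edgeR quasi-likelihood) and bqt2 by 3.35 (8.17e-08), and 9 of 12 recombination genes rose (median 3.19, camera 3.93e-05, adjusted p = 0.348 with an estimated correlation) with 6 of 7 horsetail genes. At 1 to 3 h 10 of 12 recombination genes stood above vegetative cells (2.70, 0.000216, adjusted p = 0.413 with an estimated correlation). At 4 to 6 h 4 did (0.74, 0.16), when rec8 stood at −0.28 (0.645), and at 7 to 8 h 2 did (0.76, 0.196). In the stranded column more of them stayed above vegetative cells, 10 of 19 at 4 to 6 h (1.26) and 9 of 19 at 7 to 8 h (1.04). Mmi1 targets passed in 11 of 12 in starved cells (2.23), 9 at 1 to 3 h (1.74) and 4 at 4 to 6 h.

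Single nutrient genes also fell. The transporter and assimilation genes isp4 (−3.26, 2.08e-09) and gln1 (−3.80, 2.8e-11) lay below vegetative cells at 1 to 3 h by edgeR, and lys12 (−3.45, 2.23e-08) at 7 to 8 h. Ribosome biogenesis genes fell in starved cells, 18 of 21 (median −0.98, 1.39e-08, adjusted p = 0.181 with an estimated correlation), and likewise at 1 to 3 h (17, median −1.06) and 4 to 6 h (17, median −1.07). Of 16 core stress genes 8 rose and 1 fell at 7 to 8 h (median 1.09, 0.0721).

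A shared loss of the Cul4 and Ddb1 ligase predicts like changes in both deletions. Against the ubi4 deletion, and from different libraries, changes in the cul4 and ddb1 deletions correlated at 0.79 across 5713 genes (0.87 with the libraries exchanged), which are not independent replicates. The bound of 0.3 written beforehand was met. It is left open all the same, because the ubi4 and ddb1 deletions against the cul4 deletion reached 0.58 (cul4 and ubi4 against ddb1 gave −0.07), so part of the value may come from the shared reference strain.

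Other splits of the same libraries were counted, the real one included. For loss of Pir1 in vegetative cells 4 of 100 splits gave at least the real 27 genes, and the highest other gave 1597, which points to a structure of the samples, the backgrounds. Those splits mix the backgrounds that the fit keeps apart. Within backgrounds, 48 splits can be made, and the highest other gave 1 gene. The real split alone is 2.08% of them, the lowest share that can be reached, so chance is unlikely on that count but not excluded. In the tor2-ts6 deletion strains splits are too few for a share under 0.05, with 27 real and 310 the highest other of 10 (3 as large), and 0 the highest other of 4 within backgrounds.

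For the course, the real count was the highest of 100 splits for red1 (1835, highest other 347), pir1 (2360, 655) and red1 against pir1 (2887, 1534), so that 1 split was as large. Within times it was the highest of 100 as well, with 1303, 1909 and 2242 the highest others. Chance in the grouping of libraries is unlikely on these counts, but the times of a strain are not stated to be separate cultures. A single culture, strain or batch that stands apart would give the same, so the splits leave those open. With the same limit, 1 split was as large for starved cells (2256, highest other 1801), 1 to 3 h (3080, 2146), 4 to 6 h (3596, 2643), 7 to 8 h (3142, 2199) and the phase differences of pir1 (447, 126). For the phase differences of red1, 3 of 100 splits gave 497 or more, the highest other being 714.

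Marker genes varied within the wild-type course, with mfm1 at 2.07 to 1990 CPM and ura4 at 85 to 505, against ura4 at 29.6 to 104 in the red1 deletion and 30.9 to 148 in the pir1 deletion. In h90 cells ura4 stood at 0.0961 CPM in wild type and 35.7 in tor2-ts6. It stood at 0.706 in the ubi4 deletion and 45.7 with Pir1 deleted as well. The cul4 deletions stood at 110 and 108 and the ddb1 deletions at 48.8 and 48.7. What these ura4 differences add to the h90 comparisons was not tested. No library is a copy of another, the closest pair, ubi4 deletion with and without Pir1, having a chi-square per gene of 19.94.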
